A study of Mus musculus with 2 samples.

How the data were processed

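RNA was measured in 2 sequencing libraries made from livers of mouse embryos (strain B6NCrl) at embryonic day 11.5. Per the labels, the libraries are 2 biological replicates of a single kind of sample, and each tissue sample was pooled from male and female embryos. The label of replicate 1 names 109 embryos. Per the labels, the starting material was total RNA above a size limit, extracted with the Ambion mirVana kit, with spike-in RNAs added, and the amount entering each library was 1 cell-equivalent, processed by a SmartSeq protocol. SmartSeq copies polyadenylated RNA into cDNA from its 3' end and amplifies it by PCR. The assay title given in the labels calls the libraries single-cell RNA-seq, while the source is pooled tissue. Both libraries therefore belong to 1 group, and the labels give no contrast between conditions.

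Each library came with a table per gene and a table per transcript. The deposited expected counts are estimated read counts that need not be whole, and 4.55% of the rows in replicate 1 and 4.32% in replicate 2 held a fractional count. The deposited TPM values, a length-normalised relative abundance, are estimated counts divided by effective length and scaled to the same fixed sum over all rows of each library. The deposited FPKM values are scaled for length and depth in the same way without that fixed sum. Deposited posterior mean TPM values, another estimate from the same tables, were used as an alternative. The deposited effective length, in bases, and the deposited percent of a gene's abundance assigned to each transcript were also read. Per the file headers, the columns hold these estimates with posterior means and credibility bounds, and the genome assembly is mm10 per the labels, with release M4 of the GENCODE annotation. The aligner, the quantification program and their versions are not given in the sources used here.

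The gene tables held 69691 rows, of which 43346 carried Ensembl mouse gene identifiers, 97 were spike-in sequences and 26248 had numeric identifiers with a median length of 73 bases. Spike-ins and numeric rows stayed in the TPM totals and out of the comparisons of genes. Symbols, gene types and mm10 coordinates were taken from release M21 of the annotation, a later release than that of the tables, by matching identifiers without their version suffix. Of the Ensembl rows, 42462 matched and 884 did not. The unmatched rows held 0.154% of TPM in replicate 1 and 0.172% in replicate 2. List members whose symbol had no match were not analysed here.

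The total expected count was 33289699 in replicate 1 and 32607453 in replicate 2. A gene without reads was limited by counting to 3 reads, or a CPM of 0.0901 in replicate 1 and 0.092 in replicate 2. These limits cover read counting error only, because PCR copies of a molecule are not independent molecules. The intervals below cover sampling of genes only and treat genes as independent, which they are not. The replicates were compared before averaging. Over 11213 genes with at least 20 reads in sum, chi-square per degree of freedom was 813, so they were not 1 library entered again.

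With 1 group and 1 library per replicate no test between groups and no p-value per gene can be computed. Levels were therefore given per replicate or as mean ± SD (n = 2). A gene was called detected at a TPM of at least 1. Correlations across genes used log2(TPM + 1) for genes with a mean TPM of at least 1, and carry no p-value since genes are not independent replicates. Differences between libraries were log2 ratios of replicate 2 over replicate 1 with a pseudocount of 1, centred on their median, for genes with a mean TPM of at least 10. On this scale the differences of low genes are understated. A 2-fold rule of size was applied without a test. The share of genes detected in both libraries has an exact Clopper-Pearson 95% interval.

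Gene lists for cell types, pathways and RNA classes were fixed before the data were examined, 37 in all. A list's level was the median over its members of the mean log2(TPM + 1). To describe whether a list's members differed between the libraries, the median centred log2 ratio of members with a mean TPM of at least 1 was ranked among 10000 random lists of the same size matched on mean expression in 20 bins. This was done for the 31 lists with at least 3 such members, and a percentile outside 2.5 to 97.5 was counted. It describes these libraries and is not a test of biological difference. The leading transcript of a gene was the transcript with the highest TPM, compared for genes with a mean TPM of at least 10 and at least 2 annotated transcripts.

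Named genes followed a rule fixed at the same time. They are the 15 genes with the highest mean TPM, the 3 highest members of each list with up to 3 members under TPM 1 in both libraries as contrast, all globins and sex-linked markers, the 5 genes with the largest ratio in each direction, and up to 10 list genes whose leading transcript differed. Alb and the members of a second heart list were named outside this rule, after their values were seen. Some genes that the rule would name are not reported here.

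The procedures were tested on simulated libraries of 10351 genes in which molecules were drawn at 20 TPM per molecule. In them, 200 genes, all with a mean TPM of at least 100, were raised 4-fold. Of the raised genes, 96.5% passed the 2-fold rule, as did 13.4% of unchanged genes with a TPM of at least 100. Of 200 random lists of 12 unchanged genes, 6% fell outside the central 95%, and 100% of 100 lists of 12 raised genes lay above it. The simulation does not show how often raised genes of lower level, or smaller lists, would be found. It held no spread other than molecule sampling and read counting. The genes of the 2 libraries spread more, by 26.8 to 45.6 TPM per molecule under the same model, so error rates there can be higher. The estimate of TPM per molecule returned 19.7. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Alternatives of threshold, pseudocount, unit, gene set, centring and replicate are given at the end. The second heart list of 24 genes, tested in the closing section, was written before its values were seen.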

Results

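The series measured the RNA of embryonic day 11.5 mouse liver, a stage at which the liver is both a forming organ of hepatoblasts, the precursors of hepatocytes and bile duct cells, and a site of blood formation. There were 2 libraries, 1 from each of 2 biological replicates of pooled embryos, with a total expected count of 33289699 in replicate 1 and 32607453 in replicate 2. Each library was made from 1 cell-equivalent of RNA. Spike-in RNAs took 5.83% of TPM in replicate 1 and 7.68% in replicate 2. With no second condition, the comparisons were of gene groups within the tissue and of the replicates with each other.

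The 5 genes with the highest TPM were all globins. Together the embryonic and adult globins took 9.34% ± 0.646 of all TPM (SD, n = 2). Hba-a2, an adult alpha globin (chromosome 11, 32296489 to 32297298, mm10), was the highest gene at 30190 ± 2315 TPM (n = 2), and its near copy Hba-a1 (chromosome 11, 32283511 to 32284465) stood at 15162 ± 454. Hbb-y, the embryonic beta-like globin of primitive red cells (chromosome 7, 103851749 to 103853216), was second at 16815 ± 876 TPM. The adult beta globins Hbb-bt and Hbb-bs had 11674 ± 872 and 8536 ± 1642 TPM. The embryonic Hba-x and Hbb-bh1 had 6345 ± 120 and 4691 ± 178 TPM. Reads of Hba-a1 and Hba-a2, and of Hbb-bt and Hbb-bs, can be split between near-identical copies, so their separate levels are uncertain while their sums are less so.

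The sum of embryonic globins was 0.425 ± 0.0164 of the sum of adult globins (SD, n = 2). The balance differed between the gene families. Among beta-type globins the ratio of embryonic to adult was 1.07 ± 0.0808, and among alpha-type globins it was 0.14 ± 0.0059. These ratios lay apart by far more than the spread between replicates. Hbb-y exceeded Hbb-bh1 by 3.58 ± 0.0506 times. The ratio of alpha-type to beta-type TPM was 1.24 ± 0.0369.

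Red cell genes other than globins were detected throughout. All 19 analysed members of the erythroid list had a TPM of at least 1 in both libraries, with a median log2 level of 6.89. Ermap, a red cell membrane protein, had 398 TPM in replicate 1 and 386 in replicate 2. Rhd, a blood group antigen gene, had 196 and 167. All 8 haem synthesis genes were detected in both libraries, among them Alad at 350 and 473 TPM and Urod at 391 and 270. Of 17 transcription factors of blood formation, 12 were detected in both libraries. Gfi1b had 171 and 131 TPM, Lmo2 181 and 85.9, and Gata1, the central erythroid factor, 237 and 51.4. Spi1, a myeloid factor, had no read in either library.

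The hepatoblast list took 1.36% ± 0.0877 of TPM (SD, n = 2), and 19 of its 22 members were detected in both libraries, with a median log2 level of 7.32. Afp, the fetal serum protein alpha-fetoprotein (chromosome 5, 90490737 to 90508907), had 4443 ± 604 TPM and ranked 15th of all genes. Apoa2, an apolipoprotein, had 2514 TPM in replicate 1 and 2201 in replicate 2, and Trf, the iron carrier transferrin, 1855 and 1760. Afp exceeded Alb, the albumin gene, by 7.32 ± 1.11 times. The summed TPM of the hepatoblast list was 5.9 ± 0.168 times that of the erythroid list, and globin TPM was 6.87 ± 0.0318 times hepatoblast TPM.

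Secreted liver products were detected, and most enzymes of mature hepatocytes were not. Of 10 apolipoprotein and lipid transport genes, 8 were detected in both libraries, among them Apoa1 at 1449 and 1527 TPM and Apoe at 875 and 1024. Apoa4 and Apoc3 had no read. Of 14 coagulation genes, 9 were detected in both libraries, led by Serpinc1, the antithrombin gene, at 192 and 395 TPM, Fgg at 124 and 202, and Fga at 177 and 142. F5 and F9 had no read. Of 10 complement genes, 2 were detected in both, C3 at 52.2 and 35.3 TPM and Cfi at 13.2 and 29.6. Of 16 mature hepatocyte genes, 12 were under TPM 1 in both libraries, including the cytochrome P450 genes Cyp3a11 and Cyp1a2, which had no read. Glul and Ass1 were detected in both, with 71.1 and 38.6 TPM in replicate 1 and 33.4 and 57.5 in replicate 2. None of the 8 bile acid genes had a TPM of at least 1, and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, Cyp8b1 and Cyp27a1 had no read. Such genes were not detected in these libraries, which does not show that they are absent.

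Liver transcription factors were measured near the limit of these libraries. Of 18, 4 were detected in both, 5 in replicate 1 alone and 9 in neither. Hhex had 33 and 71.1 TPM and Gata4 21.8 and 18.8. Hnf4a, a central hepatocyte factor, had 34.8 TPM from 1860 reads in replicate 1 and no read in replicate 2. Foxa1 was under TPM 1 in both. The bile duct list had no member detected in both libraries, and Krt7 was at 25.4 TPM in replicate 2 with no read in replicate 1.

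Genes of other blood lineages were present. Megakaryocyte genes were led by Pf4, platelet factor 4, at 754 and 998 TPM, with Ppbp at 102 and 128 and Itga2b at 59.6 and 34.1, and 4 of 9 members were detected in both libraries. Of 15 macrophage genes, 7 were detected in both, with Fcer1g at 141 and 64.4 TPM, Lyz2 at 140 and 41.9, and the complement component C1qb at 107 and 56.6, whereas Cd68, Cd163 and Vsig4 had no read. Of 9 granulocyte and mast cell genes, 4 were detected in both. S100a8 had 281 and 288 TPM, S100a9 395 and 64.5, and Mpo, myeloperoxidase, 153 and 127. Of 12 stem and progenitor genes, 4 were detected in both, with Cd34 at 27.8 and 57.8 TPM, Kit at 29.7 and 30.7, and Runx1 at 23.2 and 19.5. All 8 lymphoid genes were under TPM 1 in both libraries, among them Cd3e and Cd79a, which had no read.

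Genes of vascular and connective tissue cells were detected as well. Of 14 endothelial genes, 7 were detected in both libraries, led by Lyve1 at 44.6 and 22.6 TPM, Esam at 23.2 and 36.3, and Egfl7 at 20.6 and 30.7. Of 13 mesenchymal and stellate cell genes, 8 were detected in both, with the collagen gene Col3a1 at 60.7 and 150 TPM, Dcn at 49.3 and 95.2, and Lum at 28.8 and 108. In the mesothelial list Wt1 had 12.1 and 34.6 TPM. Markers of pancreas, gut and lung were all under TPM 1 in both libraries, including Pdx1, Ptf1a and Cpa1. The list of neural, skin and kidney markers had 1 detection, Stmn2 at 8.19 TPM in replicate 1. Heart and muscle genes were seen mainly in replicate 2. Myl7, an atrial myosin light chain, had no read in replicate 1 and 93.5 TPM in replicate 2, Myl2 had no read and 36.5, and Myh6 had 6.62 and 38.7.

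**Figure D1:**
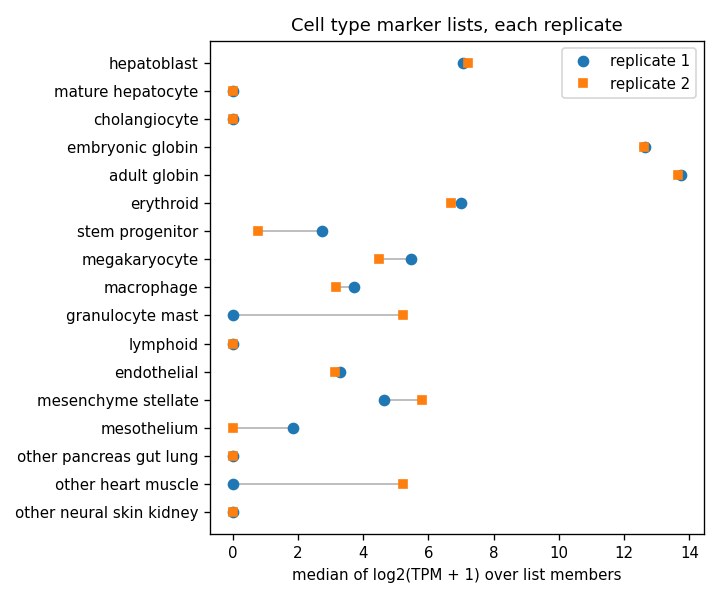
Median log2(TPM + 1) over the members of each cell type marker list, with replicate 1 as circles and replicate 2 as squares joined by a line. Adult and embryonic globins lie highest, the hepatoblast and erythroid lists follow near 7, and the heart and muscle list lies at 0.01 in replicate 1 and 5.22 in replicate 2.

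Proliferation genes were uniformly detected, 18 of 18 in both libraries, with a median log2 level of 7.57. Cdk1 had 503 and 337 TPM, Pcna 349 and 339, and Birc5 227 and 432. Ribosomal protein genes took 10.1% ± 0.27 of TPM (n = 2), with 80 of 83 detected in both. Mitochondrial coding genes took 2.73% ± 0.155, led by mt-Atp6 at 7032 ± 38.8 and mt-Atp8 at 5129 ± 147 TPM. This share counts reads assigned to the 13 listed genes only. Unprocessed pseudogenes, the class of Gm28437 below, took 1.36% of TPM in replicate 1 and 1.54% in replicate 2. Whether mitochondrial reads were assigned to them, which would lower this share, was not tested. Of 14 analysed cholesterol synthesis genes, 12 were detected in both libraries, with Fdps at 248 and 254 TPM and Msmo1 at 166 in each. Imprinted genes were well represented, 14 of 18 in both, with Mest at 629 and 721 TPM, H19 at 601 and 600, and Igf2, a fetal growth factor, at 563 and 398. Of the niche factors for blood stem cells, Igf2 belonged to that list too, Kitl had 62.6 and 4.09 TPM and Cxcl12 42 and 8.84, while Epo had no read. Of 10 stress and immediate early genes, 7 were under TPM 1 in both libraries. Fos and Fosb had no read and Jun had 0.36 and 0.01 TPM, while Dnajb1 had 67.8 and 19.3, Junb 15.1 and 0, and Ier2 0.19 and 8.54.

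Sex-linked genes of both sexes were present. Xist, expressed from the inactive X chromosome, had 21.3 and 19.7 TPM. The Y-linked Ddx3y had 41.4 and 8.93, Kdm5d 9.68 and 0, Uty 6.37 and 0, and Eif2s3y 0 and 8.94. Among nuclear and short RNAs, Malat1 had 2371 and 3302 TPM. Rn7s1 and Rn7s2 held identical values of 769 and 1164 TPM, so their reads were shared between copies. Hist1h2ap, a replication-dependent histone with near-identical relatives, had 4733 ± 882 TPM.

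Some of the 15 highest rows were not independent genes. Gm22133, annotated as a microRNA (chromosome 7, 45458089 to 45458197), had 8281 ± 906 TPM from only 2637 and 2245 reads over an effective length of 10 bases. It lies within Ftl1, the ferritin light chain gene (chromosome 7, 45457944 to 45459884), which had 7801 ± 686 TPM from 210505 reads in replicate 1. Gm28437, a pseudogene on chromosome 1 at 24613189 to 24613971, had 7505 ± 159 TPM. The remaining high gene, Ppia, had 5457 ± 788 TPM.

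The replicates were then compared gene by gene. At a TPM of at least 1, 8922 genes were detected in replicate 1 and 8342 in replicate 2. Of 10783 detected in either, 6481 were detected in both, a share of 60.1% (exact 95% interval 59.2 to 61%). A further 2441 were found in replicate 1 alone and 1861 in replicate 2 alone. Across the 10351 genes with a mean TPM of at least 1, Pearson r of log2(TPM + 1) was 0.493 and Spearman rho 0.503. Genes are not independent replicates, so no p-value applies. With all 43346 genes r was 0.813, but 29707 of these were listed at 0 in both libraries and count as agreement. With a pseudocount of 0.1, over the genes with a mean TPM of at least 1, r was 0.281.

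**Figure D2:**
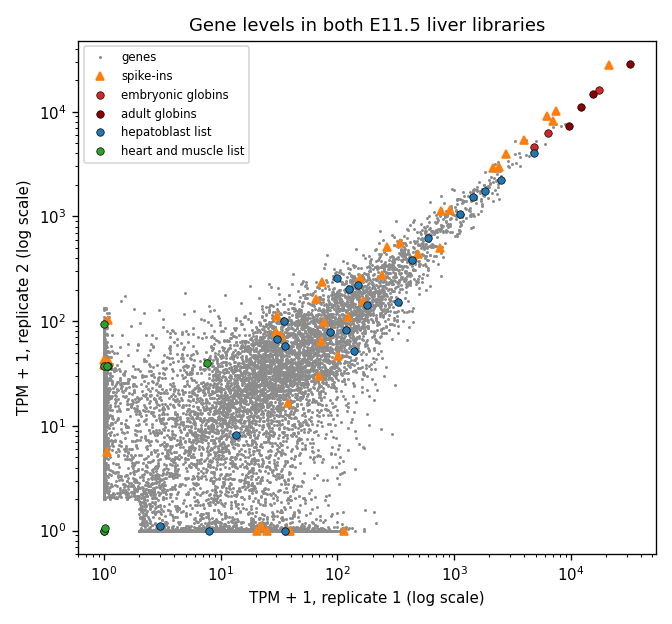
TPM + 1 of each gene in replicate 1 (x axis) and replicate 2 (y axis), both on log scales, for genes with a TPM of at least 1 in either library, spike-ins and members of 4 marker lists. Abundant genes lie near the diagonal, while many genes below about 100 TPM lie along an axis, present in 1 library and at or near 0 in the other.

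The disagreement depended on level. Of genes at TPM 10 to 20 in 1 library, 35.6% were under TPM 1 in the other, and the share fell to 10.1% at 50 to 100 and 2.19% at 100 to 200. None of 327 observations at 500 to 1000 and none of 311 at 1000 or more was missed. The median absolute log2 difference was 1.03 over the 6801 genes with a mean TPM of at least 10, and 0.21 over the 151 genes of mean TPM 1000 or more. By the 2-fold rule, 1716 genes were higher in replicate 2 and 1758 in replicate 1. When the ratio was centred on the spike-ins, the numbers were 1337 and 2266, so the calls higher in replicate 2 made up 37.1% of the total against 49.4%.

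**Figure D3:**
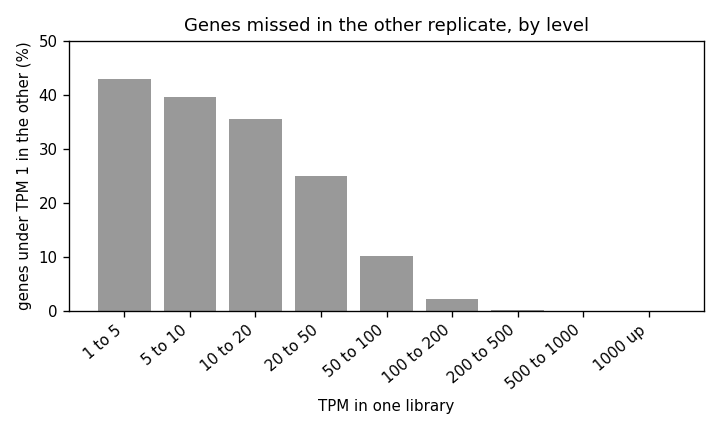
Percent of genes under TPM 1 in the other library (y axis, from 0), by TPM in the library where they were observed (x axis), with both directions pooled. The share is 43% at TPM 1 to 5 and 0% from TPM 500.

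At the extremes, many reads in 1 library stood against few or none in the other. Lrpap1 had 134 TPM from 3869 reads in replicate 2 and none in replicate 1. Its share of reads was at least 1317-fold higher against a floor of 3 reads per library. Oxld1 and Ppil3, likewise unread in replicate 1, were at least 947-fold and 1086-fold higher in replicate 2. Praf2 and Zdhhc12 had 4807 and 3999 reads in replicate 2 and 1 read each in replicate 1. In the other direction Ppif had 7188 reads in replicate 1 and none in replicate 2, at least 2347-fold higher, and Trappc2l, with 2106 reads against none, at least 688-fold. Vta1 had 4900 reads against 1, Nelfcd 10915 against 11 and Gm49405 4473 against 10. All these folds compare shares of reads and allow for read counting error only. PCR copies of a molecule are not independent, so the folds are not lower bounds on a difference in RNA. With 1 library per replicate these differences have no replicate check.

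Of 31 lists compared between the libraries, 3 lay outside the central 95% of matched random lists, against 1.55 by chance. The 10 mesenchymal and stellate cell genes compared had a median log2 ratio, replicate 2 over replicate 1, of 1.33 at percentile 98.5. The 5 heart and muscle genes compared had a median of 5.19 at percentile 98.9. The 4 niche factor genes had a median of -2.81 at percentile 1.94. Hepatoblast, erythroid and globin lists lay within that range, at percentiles 25.7, 28.2, 35.3 (embryonic) and 25.1 (adult). On depth-scaled expected counts the heart and muscle list alone remained outside, and with a pseudocount of 0.1 the niche factor list fell within the range.

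The estimated leading transcripts differed between the libraries too. Of 4445 genes with a mean TPM of at least 10, at least 2 annotated transcripts and reads in both libraries, 2776 had the same leading transcript, a share of 62.5% (exact 95% interval 61 to 63.9%). The share was 44.8% at a mean TPM of 10 to 20 and 92.9% at 500 or more. Among 30 hepatoblast, erythroid and transcription factor genes compared, 9 had different leading transcripts: Hemgn, Fgg, Tfrc, Bcl11a, Slc25a37, Ikzf1, Apob, Epb42 and Gata4. For Hemgn, an erythroid gene, the leading transcript of replicate 1 held 99.3% of the gene's abundance there and 39.4% in replicate 2. For Apob, the main lipoprotein gene, the leading transcript of replicate 2 held 87.8% there and 35.6% in replicate 1. Apob had 7973 reads and 29.1 TPM in replicate 1, and 5060 reads and 66.7 TPM in replicate 2. Tfrc went the other way, with 8950 reads and 127 TPM, then 13291 reads and 113 TPM. The assignment of reads to transcripts thus affected these values. A difference in transcripts was not told apart from read assignment or sampling at 1 cell-equivalent.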

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

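The test of a single-cell origin was chosen only after the result was seen. The other tests were set before their values were computed, but conditions withholding a verdict on the heart genes were added after the counts were seen. The rows with numeric identifiers, which no comparison used, held 111 reads in replicate 1 and 26.98 in replicate 2 in sum over 26248 rows. Each sum exceeds the 3 reads that a sum of 0 would allow, which does not tell RNA of these features from misassigned reads.

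The variance of the log2 count ratio between the replicates was 5605 times its Poisson value over 9679 genes, a spread to which differences between separate pools of embryos can add. Over 39 spike-ins, which are not part of the tissue, it was 6205 times, which argues against read counting error alone. Effective length was nearly unrelated to the ratio (Spearman rho 0.0378 across 6801 genes), which argues against a length bias that differs between the libraries. A length effect common to both libraries would not show in this ratio. Sampling of few molecules at low input stays as a candidate explanation. Excess squared variation fell with mean TPM with a log-log slope of -0.78 over 7 bins, which passed the bound set beforehand. The slope was -0.73 over the 4 bins from TPM 100, where the measure is far from its ceiling. It was -0.65 over 3 bins of spike-ins. In the simulated libraries, which held molecule sampling and read counting only, it was -0.895. The slopes seen were shallower than that, so spread from other sources is not excluded. A different cell composition of the pools stays open, since 15.4% of 13 cell type lists lay outside the range of random lists, between the bounds set beforehand, while on expected counts scaled for depth 1 of the 13 did (7.69%), under the lower bound.

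Heart muscle genes of replicate 2 were examined with a second list of 24 genes. Of these, 5 were at TPM 1 or more in replicate 2 alone (Tnni3, Ttn, Pln, Myom1 and Atp2a2) and 0 in replicate 1 alone. An exact two-sided sign test gave p = 0.0625, the smallest that 5 genes allow when both libraries have equal chances. Over all genes, 2441 were detected in replicate 1 alone and 1861 in replicate 2 alone, so the chances were not equal. The test also treats the genes as independent. It therefore decides nothing on sampling at equal level in both libraries, which stays open. RNA of heart cells in the replicate 2 pool may contribute, and 5 genes reached the bound set for it, but 16 of the 24 were under TPM 1 in both libraries, Myh7 and Myl3 had no read, and Actc1 and Tnni1, which were seen in both libraries, had more TPM in replicate 1. The third gene seen in both, Tbx20, had more TPM in replicate 1 and more reads in replicate 2. The origin of the heart gene reads stays open.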

How the results depend on the processing

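All alternatives were listed before the data were examined. Of 90 alternative values for the main results, 16 say nothing on stability, because their construction kept them within the range or they count genes in 1 library in place of both. Of the other 74, 40 stayed within the spread, interval or 1.5-fold range set for them, and 34 moved. The 40 include the list comparison without centring, which shifts a list and its random lists alike. They also include the leading transcripts on transcript FPKM, which rescales all transcripts of a library alike. Neither setting could be expected to move its result, so the 40 overstate stability. A change of direction was not looked for. Without centring, 1744 genes were 2-fold higher in replicate 2 and 1739 in replicate 1, against 1716 and 1758 as reported. For results that moved, the cause was not tested beyond the construction of the setting. Genes below about 100 TPM in 1 library were often under TPM 1 in the other, which limits every statement on them. The part of sequencing depth in this was not tested.

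The share of genes detected in both libraries was 63.4% at TPM 0.1, 56.5% at TPM 5 and 62% for protein-coding genes. The correlation was 0.281 with a pseudocount of 0.1, 0.67 with 5, 0.813 with no filter, 0.403 at a mean TPM of at least 10, 0.388 on expected counts scaled for depth, 0.474 for protein-coding genes and 0.461 without globin, mitochondrial and ribosomal protein genes. The median absolute log2 difference was 1.1 centred on the spike-ins, 0.93 with a pseudocount of 5, 1.55 at a mean TPM of at least 1 and 0.59 at 50. At a mean TPM of at least 1, 3026 genes were 2-fold higher in replicate 2 and 3297 in replicate 1, and at 50 the counts were 380 and 406, over more and fewer genes.

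Without spike-ins in the total, globins took 10.01%, hepatoblast genes 1.46% and mitochondrial genes 2.93% of TPM. Among protein-coding genes the shares were 11.1%, 1.62% and 3.26%. On expected counts, not corrected for length, they were 4.31%, 1.77% and 1.67%, the embryonic to adult globin ratio 0.499 and the hepatoblast to erythroid ratio 4.46. In single replicates the globin share was 8.88 and 9.8%, and the genes detected numbered 8342 and 8922. The share of genes detected in both cannot be formed from 1 library.

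Of 37 lists, 25 had a median at or above the level of TPM 1, and 24 to 26 under the alternatives. Single list medians moved by more than the spread between libraries in 16 lists with a pseudocount of 0.1 and 19 with 5, where the pseudocount shifts the log scale itself. They did so in 13 lists on FPKM, in 9 without replicate 1 and in 13 without replicate 2. FPKM rescales all genes of a library alike. On it the housekeeping median went from 8.92 to 8.76 and the ribosomal protein median from 10.2 to 10.04. The moves on FPKM therefore need not mean instability. The megakaryocyte median went from 2.88 to 4.47 and 5.47 with either replicate left out, and that of granulocyte and mast cells from 2.68 to 5.21 without replicate 1 and 0 without replicate 2. The lists outside the range of random lists numbered 1 on expected counts scaled for depth. The same leading transcript was found for 1529 genes (78.6%) at a mean TPM of at least 50, 59.97% at 1, and 75.7% where it held over 60% in both libraries. No paired analysis was possible because there was only 1 group.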

Other observations

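The test in the last paragraph was chosen after the result was seen. Some spike-ins, like some genes, were detected in 1 library alone. Of 96 ERCC sequences, 28 were detected in both libraries, 6 in replicate 1 alone and 6 in replicate 2 alone. The median log2 ratio of the 20 spike-ins with a mean TPM of at least 100 was 0.44, so they took a larger part of replicate 2. Under a model in which each library draws whole molecules, the spread corresponded to 26.8 TPM per molecule for genes of mean TPM 100 to 200, 31.8 for 200 to 500, 29.2 for 500 to 1000, 45.6 for 1000 or more, and 23.7 for spike-ins of 100 or more.

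Each library held transcripts of many cell types. Besides the erythroid and globin lists, 8 cell type lists had at least 2 members at TPM 1 or more in both libraries: hepatoblast, mature hepatocyte, stem and progenitor, megakaryocyte, macrophage, granulocyte and mast, endothelial, and mesenchymal. This argues against RNA of a single cell as the source of each library, a reading that the assay title alone would allow, and is consistent with a 1 cell-equivalent portion of RNA from pooled tissue.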
